A study of Mus musculus with 31 samples.

How the data were processed

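Single cells from lung lobes of 10-week-old Csf1r reporter mice, collected 7 days after a sham operation, were sorted, captured on a Fluidigm C1 microfluidic chip and lysed there. Per the labels' protocols, polyadenylated RNA was reverse transcribed and amplified with a SMARTer kit, and libraries were made with Nextera XT, which cuts and tags cDNA with a transposase and does not mark the strand. Reads of overlapping or antisense genes can therefore not be told apart, and near-identical copies such as Hspa1a and Hspa1b share reads. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic and RSEM were used with the GRCm38 genome build. The order and settings of these tools, the aligner, the annotation release and any filter on cells are not given in the sources used here.

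The authors deposited 1 table of RSEM expected counts, which are estimated read counts per gene and need not be whole, and 1 table of FPKM values, which are fragment counts scaled to transcript length and to the mapped fragments of the library. FPKM is thus already scaled to each cell's depth and to gene length. No molecular identifiers were used, so amplified copies of 1 molecule are counted as several reads. The count table held 75 columns, of which 31 matched the titles of the 31 samples and 44 columns matched none and were not used. Both tables held 47069 genes by Ensembl identifier. Of these, 46488 matched a symbol in the gene name table, and identifiers without a symbol held 0.274% of counts. Gene types and coordinates were taken from GENCODE M21, which is on the same build, and coordinates are 1-based. No 2 libraries held identical counts, and the highest Pearson correlation between 2 cells was 0.564.

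The 31 cells belong to 1 group and the labels name no animal. The group therefore counts as 1 sample, and no test between groups or of genes between clusters was made. The minimums, lists, gene pairs, clustering and naming rule were fixed before the data were examined. A gene counted as present in a cell at FPKM 1 or more. Shares of cells are given with exact Clopper-Pearson 95% intervals, which cover counting error over cells only, and 0 of 31 cells allows a share of up to 11.2%. The lists covered 343 genes in 19 cell type lists and 13 functional lists. A cell met a list if it held at least 50% of its members. No doublet caller was run on 31 cells, and cells that met 2 lists were counted instead. Mean ± SD values are taken over cells and describe these cells.

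Cells were clustered on log2(FPKM + 1) of the 1000 most variable genes among those present in at least 3 cells, without mitochondrial genes. Values were centred and reduced to 5 principal components, and Ward linkage on Euclidean distance was used. The number of clusters from 3 to 6 with the highest mean silhouette width was taken, and k-means with 100 starts was run beside it. The width was set beside that of 100 data sets with each gene's values shuffled over cells. For each functional list, clusters were made again without the list's genes and numbered after the clusters they overlapped most. Clusters were named from fixed marker lists only. The genes named are the 10 with the largest mean log2 difference per cluster among genes in at least 75% of its cells, the 10 with the highest mean FPKM, the 10 with the largest variance, the sort genes, the 4 members of each list found in most cells and members found in none. The genes of the fixed pairs are named too. The results of some genes that this rule names are not reported here. Cxcl2, Egr1, Fcer1g, Hp, Cd177, Igf1, Igkc, Msr1, Ptgs2, Thbs1 and Timp2 fall outside this rule and were chosen after their values had been seen, as were the genes plotted.

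The clustering was tested on simulated cells with the real gene means and depths, 47069 genes and 200 changed genes in each of 3 clusters of 15, 10 and 6 cells. With 16-fold changes a median of 31 of 31 cells was placed correctly at 3 clusters, and with 4-fold changes 24, or 31 after thinning to equal depth. The highest silhouette width picked 3 clusters in 4 of 10 sets with 16-fold changes and in 0 of 10 with 4-fold changes, but in 7 of 10 sets without clusters, so the number of clusters is not well determined by it. In 10 sets without clusters the width at 3 clusters was 0.403 to 0.564, or 0.115 to 0.196 after thinning.

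Alternatives fixed in advance were FPKM 5 or more, expected counts of 1 or more and 10 or more, counts rounded to whole numbers and every cell thinned to the 120829 of the shallowest, cells with at least 1000 genes, other pseudocounts (0.1 and 10), counts and FPKM each scaled to equal library totals, other gene filters and numbers of variable genes (500 and 3000), 10 or no principal components, average linkage on correlation, k-means, 2 to 6 clusters, clusters without stress and cell cycle genes, and genes detected regressed out. A minimum of 50 FPKM and the 21 libraries with at least 80% of counts on nuclear protein-coding genes were added after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.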

Results

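The transcriptomes of 31 single cells from the lungs of adult mice were measured 7 days after a sham thoracotomy, an operation in which the chest is opened and closed again. The mice carried a green fluorescent protein reporter of Csf1r, the gene of the receptor through which the growth factor CSF1 sustains monocytes and macrophages. Cells were sorted on the leukocyte antigen CD45, the reporter and the macrophage antigen F4/80, and the sort label also names the neutrophil antigen Ly6G without its sign. The question posed was which macrophage populations the lung holds at this time. All 31 cells form 1 group and the labels name no animal, so the group was treated as 1 sample. Cells are not replicates, no p-value was computed, and every interval covers counting error over cells only.

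The 31 libraries fell apart by their share of protein-coding reads. Medians of myeloid genes such as Lyz2 and Tyrobp were much lower in 10 of them, though single libraries overlapped. Tyrobp reached 3703 FPKM in D10 of these 10, against 202 FPKM in F11 of the other 21. In the other 21, 87.4 to 95.6% of expected counts (median 92.2%) fell on nuclear protein-coding genes, against 32.8 to 61.6% (median 47.5%) in the 10. The 10 instead placed 32.7 to 45.1% of counts on long noncoding, pseudogene, antisense and unassigned transcripts, against 1.89 to 6.84% in the 21. Their mitochondrial share ranged from 0 to 19.9%, against 0.717 to 4.78% in the 21. Total expected counts ran from 120835 to 4059833 per cell over all 31, with a median of 373305 in the 10 and 1479639 in the 21, and the ranges of both overlapped. A median of 2486 genes per cell (range 1856 to 3574) reached 1 FPKM. The 10 libraries had more such genes (median 3278) than the 21 (median 2407). Since FPKM is scaled to depth, 1 read gives a higher FPKM at fewer counts, so these 2 medians cannot be compared directly. The dividing line of 80% was set after these shares had been seen, and counts below are for all 31 cells unless the 21 are named.

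**Figure D1:**
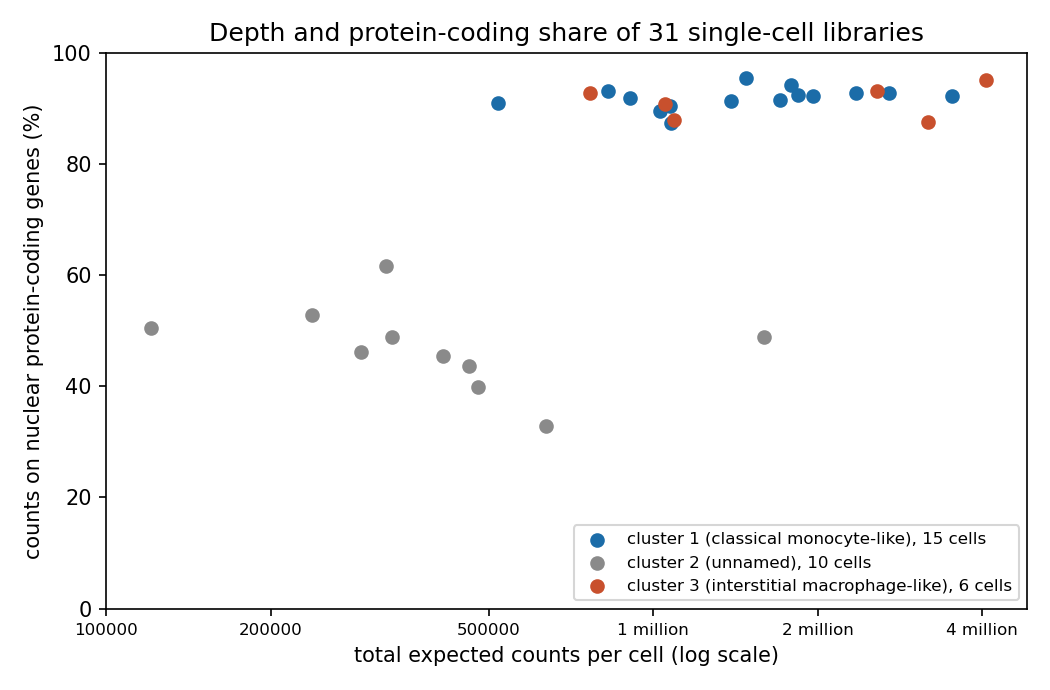
Each point is 1 cell, with its total expected counts on a log axis and the percent of counts on nuclear protein-coding genes on the vertical axis, coloured by cluster. The 10 cells of cluster 2 lie between 32.8 and 61.6%, and the other 21 between 87.4 and 95.6%.

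Of the genes named in the sort, Csf1r, Ptprc and Adgre1 were found in most of the 21 libraries and Ly6g in 7 of them. Csf1r (ENSMUSG00000024621; GRCm38 chromosome 18, 61100598 to 61132149) was present in 27 of 31 cells (87.1%, exact Clopper-Pearson 95% interval 70.2 to 96.4%) and in 20 of the 21, at a median of 103 FPKM in the 21. Ptprc (ENSMUSG00000026395; chromosome 1, 138062861 to 138175708), which encodes CD45, was present in 24 of 31 cells (77.4%, 58.9 to 90.4%) and in 20 of the 21. Adgre1 (ENSMUSG00000004730; chromosome 17, 57358691 to 57483527), which encodes F4/80, was present in 16 of 31 (51.6%, 33.1 to 69.8%) and in 15 of the 21. Ly6g (ENSMUSG00000022582; chromosome 15, 75155240 to 75159126) was present in 7 of 31 cells (22.6%, 9.59 to 41.1%), with a highest value of 115 FPKM. At 50 FPKM or more, Ptprc was found in 22 of 31 cells, Csf1r in 14, Adgre1 in 11 and Ly6g in 1. Among pan-myeloid genes, the lysozyme gene Lyz2 was found in 28 of 31 cells and the signalling adaptors Tyrobp and Fcer1g in 25 and 23, both in 21 of the 21. Median Lyz2 was 22467 FPKM in the 21 and 96.7 FPKM in the 10.

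Classical monocyte genes were the most widely met of the 19 cell type lists. At least 50% of the classical monocyte list was present in 12 of 31 cells (38.7%, 21.9 to 57.8%), all of them among the 21. The interstitial macrophage list was met by 5 cells (16.1%, 5.45 to 33.7%) and the nonclassical monocyte list by 2 (6.45%, 0.791 to 21.4%). Cell G8 met both monocyte lists and was the single cell to meet 2 lists. Of the 13 cells that met no list, 10 were the low-coding libraries. No cell met the alveolar macrophage list, which allows a share of up to 11.2% from all 31 cells, or 16.1% from the 21. Siglecf, Marco, Car4, Fabp1, Krt79, Plet1, Atp6v0d2, Cidec, Pparg, Ctsk and Krt19 of that list were found in no cell, while Cd9 and Lpl were found in 30 and 27 cells, and in 20 and 17 of the 21.

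The lists for dendritic cells of types 1 and 2, plasmacytoid dendritic cells, neutrophils, eosinophils, mast cells or basophils, B cells, T cells, NK cells, platelets, erythroid cells, alveolar and airway epithelium, endothelium and fibroblasts were also met by 0 of 31 cells. All 8 NK cell genes and all 6 erythroid genes, among them Ncr1, Nkg7, Hba-a1 and Alas2, were found in no cell. Single members of other lineages were found in either set of libraries. The neutrophil chemokine receptor gene Cxcr2 was present in 10 of the 10 (12.2 to 91.6 FPKM) and in 10 of the 21 at up to 9.74 FPKM. Ms4a1, which encodes the B cell antigen CD20, was present in 10 of the 10 and in 1 of the 21, the endothelial adhesion gene Pecam1 in 10 and 2, and the dendritic cell receptor gene Xcr1 in 9 and 1. Ighm, which encodes the constant region of IgM, was present in 0 of the 10 and 7 of the 21, Hopx in 0 and 8, Irf8 in 1 and 8 and Tcf4 in 3 and 13. The neutrophil genes S100a9, Retnlg, Ltf and Lcn2 were found in no cell.

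Hierarchical clustering gave 3 clusters. Cluster 1 held 15 cells (48.4%, 30.2 to 66.9%) and is called classical monocyte-like. Its leading genes were S100a6, Lgals3, Plac8, Gngt2, S100a4, Ifitm3, Atp5l, Rpl19, Ly6e and Ifi27l2a, of which Plac8 and S100a4 are classical and Gngt2 nonclassical monocyte markers. Cluster 2 held 10 cells (32.3%, 16.7 to 51.4%), which were the 10 low-coding libraries. It was led by Gm26870, Gm10718, Gm38356, Gm10800, Gm42857, Gm21750, Gm22398, Gm28313, Gm26268 and Gm13722, predicted genes that belong to no marker list, and it was left unnamed. Of these, Gm10718, Gm10800 and Gm21750 are typed as protein-coding and averaged 4191, 9211 and 4770 FPKM in cluster 2. Their counts are therefore part of the protein-coding share of these 10 libraries. Cluster 3 held 6 cells (19.4%, 7.45 to 37.5%) and is called interstitial macrophage-like, though 4 of the 6 met the interstitial macrophage list and the fifth cell to meet it, C7, lay in cluster 1. Of that list, C1qb was present in 6 of the 6 cells and C1qa, C1qc and Pf4 in 5 each. Folr2, Stab1, Cbr2 and Tmem119 were present in 1 of the 6 each, and Lyve1 and Cd163 in none. Cell F11 of cluster 3 had 0 FPKM of Lyz2, Adgre1, C1qa, C1qc and Pf4 and 0.99 FPKM of Csf1r. The cluster was led by the complement genes C1qb, C1qa and C1qc, the antigen presentation genes H2-Aa, H2-Eb1 and Cd74, and Pf4, Mgl2, Tmem176a and Hspa1a. Of the leading genes, Mgl2 is a member of the list for dendritic cells of type 2 or monocyte-derived cells. These genes define the clusters and are not findings about them.

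The clusters rested on 5 principal components and had a mean silhouette width of 0.499. Data sets with each gene shuffled over cells gave 0.113 to 0.189, but simulated cells without clusters gave 0.403 to 0.564 from their unequal depths, so the width alone does not set these clusters apart. With every cell thinned to 120829 counts the width was 0.523 and all 31 cells kept their clusters, while simulated cells without clusters gave 0.115 to 0.196. Those simulated cells shared 1 expression profile and had no low-coding libraries. The contrast therefore does not bear on the split between clusters 1 and 3. At 2 clusters without thinning, which set the 10 libraries apart from the 21, the width was 0.657. K-means with 3 clusters placed 29 cells alike (adjusted Rand index 0.818) and moved cells C7 and D6 from cluster 1 to cluster 3. Among the 21 libraries clustered alone into 2, 16 stayed with their cluster, where placing all 21 in 1 cluster would keep 15. The width of 0.181 lay inside the shuffled range of 0.0982 to 0.191. With the number of genes detected regressed out, 10 of those 21 kept their cluster at 3 clusters, and no cell of cluster 3 was among them. In that setting 5 of the 21 joined the low-coding libraries. At the 6 clusters which that setting chose, 15 of the 21 kept their cluster. The border between clusters 1 and 3 is therefore loose, and cluster 3 did not stand apart in every setting.

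**Figure D2:**
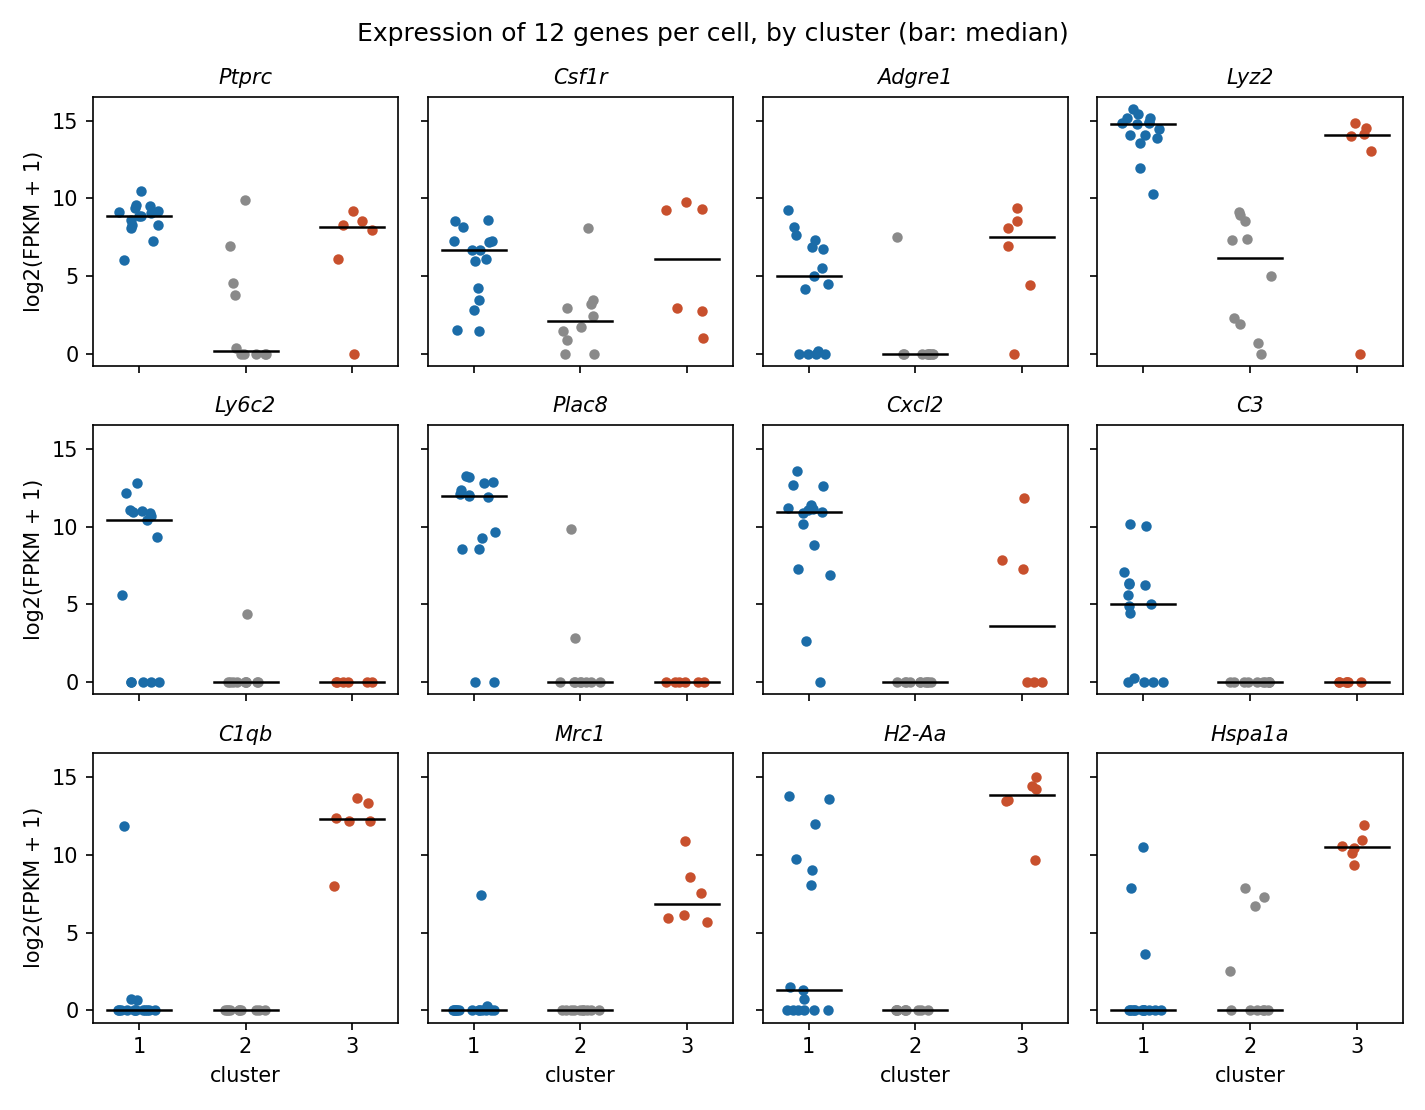
Each point is 1 cell, each panel 1 gene, with log2(FPKM + 1) on the vertical axis, the 3 clusters on the horizontal axis and a bar at the median. Ly6c2 was present in 10 of 15 cells of cluster 1 and in 0 of 6 of cluster 3, and C1qb in 1 of 15 and 6 of 6.

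Other genes of the cell type lists are described here in the same clusters. These lists were not left out of the clustering, so their genes could take part in the split and, like the leading genes, are not findings about it. Ly6c2, which encodes part of the monocyte antigen Ly6C, was present in 10 of 15 cells of cluster 1 and in 0 of 6 of cluster 3, at medians of 1397 and 0 FPKM. Haptoglobin (Hp) was present in 12 of 15 and 0 of 6, and the fibronectin gene Fn1 in 13 of 15 (median 221 FPKM) and 3 of 6 (1.32 FPKM). The chemokine receptor gene Ccr2 did not divide the clusters in this way, at 13 of 15 and 3 of 6 cells with medians of 221 and 345 FPKM. In cluster 3, the mannose receptor gene Mrc1 was present in 6 of 6 cells (50.3 to 1887 FPKM) and in 1 of 15 of cluster 1. The apolipoprotein gene Apoe was found in both, with medians of 1278 FPKM in cluster 1 and 13592 FPKM in cluster 3. Cx3cr1 was present in 4 of 15 and 5 of 6 cells.

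Antigen presentation and complement genes were more widely found in cluster 3 than in cluster 1 when the clusters were made without them. Leaving out either list left 30 of 31 cells in their clusters, and genes of the other list stayed in. These differences are therefore not independent of the genes that lead cluster 3. Of the 11 genes for MHC class II presentation, cells held 63.6% ± 16.6 (mean ± SD over 7 cells) in cluster 3 and 40.9% ± 21.9 (14 cells) in cluster 1, a difference of 22.7 that is close to the SD of cluster 1. H2-Aa averaged 14191 ± 11949.9 FPKM in cluster 3 and 2331 ± 4845 FPKM in cluster 1, and was present in 7 of 7 and 7 of 14 cells. The protease gene Ctss and the invariant chain gene Cd74 were present in 25 and 22 of 31 cells, H2-Ab1 in 20 and H2-DMb2 in 14, of which 10 were the low-coding libraries. Of the 13 complement and clearance genes, cells held 44.0% ± 20.2 (7 cells) in cluster 3 and 19.2% ± 9.89 (14 cells) in cluster 1, a difference of 24.7 that is above both SDs. The list's parts went opposite ways, since C1qb averaged 5532 ± 4896 and 266 ± 997 FPKM, while the central complement component C3 was present in 0 of 7 cells of cluster 3 and 10 of 14 of cluster 1. C5ar1 was found in 16 and the properdin gene Cfp in 11 of 31 cells, and Cfb and Timd4 in none.

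Every one of the 15 immediate early and stress genes was found in at least 10% of the 31 cells. Of these genes, cells of cluster 3 held 91.1% ± 10.0 (6 cells) and cells of cluster 1 60.0% ± 13.8 (15 cells), with the list left out of the clustering, a difference of 31.1 that is above both SDs and that was 19.5 with the 21 libraries clustered alone into 2. The NF-kappa B inhibitor gene Nfkbia was present in 29 of 31 cells (93.5%, 78.6 to 99.2%), the phosphatase gene Dusp1 in 27, Junb in 26 and the RNA-decay factor gene Zfp36 in 25. The heat shock gene Hspa1a was present in 6 of 6 cells of cluster 3 (1761 ± 1127 FPKM) and 3 of 15 of cluster 1 (114 ± 377 FPKM), and the transcription factor gene Egr1 in 6 of 6 and 2 of 15. All 31 cells kept their clusters without the list, so the list's difference is not independent of Hspa1a, a leading gene of cluster 3. Immediate early and stress genes can respond to tissue dissociation and sorting, and no unsorted cells were measured.

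**Figure D3:**
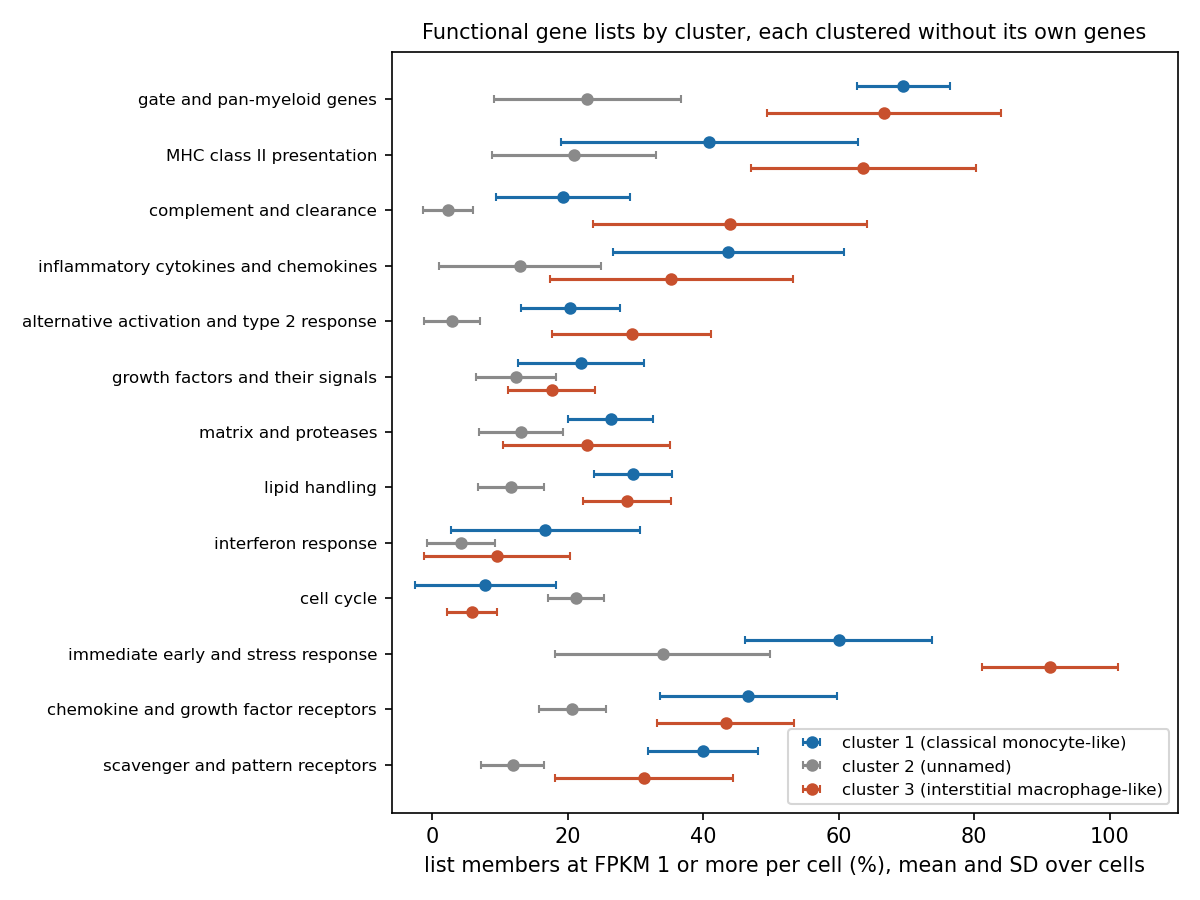
For each functional list, points give the mean percent of list members at 1 FPKM or more per cell and bars the SD over cells, for clusters made without that list's genes. Immediate early and stress genes stood at 91.1% in cluster 3 and 60.0% in cluster 1, and complement genes at 44.0 and 19.2%.

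Inflammatory mediators were found in both cluster 1 and cluster 3. The interleukin gene Il1b was present in 20 of 31 cells (64.5%, 45.4 to 80.8%), Ccl4, Tnf and the inflammasome gene Nlrp3 in 19 each, and Cxcl2 in 17, all 17 among the 21. Cells of cluster 1 held 43.7% ± 17.1 of the 17 genes (14 cells) and cells of cluster 3 35.3% ± 17.97 (7 cells), which differed by less than the spread over cells. In these clusters made without the list, median Il1b was 4529 FPKM in cluster 1 and 246 FPKM in cluster 3, median Cxcl2 2096 and 154 FPKM and median Ccl4 6496 and 937 FPKM. The order was the other way for Tnf (549 and 632 FPKM) and Nlrp3 (9.75 and 141 FPKM), and for Ccl4 it turned with the list's genes in the clustering (6146 and 9916 FPKM). Il12b and Nos2, which mark classical activation, were found in no cell, and neither were Arg1, Retnla and Irf4 of the alternative activation list. The members of that list found most often were Chil3 (14 cells), Il10ra (13), Socs3 (13) and Klf4 (10). Chil3 was present in 11 of 15 cells of cluster 1 and in 1 of 6 of cluster 3, Klf4 in 10 of 15 and 0 of 6, and Mrc1 and the lectin gene Mgl2 in 1 of 15 and 6 of 6.

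Genes for tissue repair were found unevenly. Progranulin (Grn) was present in 21 of 31 cells and 20 of the 21, Tgfb1 in 18 and Tgfbi in 17, and Vegfb, Areg and Fgf2 in none. Wnt4 was present in 14 cells, of which 10 were the low-coding libraries. Among matrix genes and proteases, Fn1 was present in 25 cells and 16 of the 21, the cathepsin gene Ctsb in 22 and 21 of the 21, and the urokinase receptor gene Plaur in 17, of which 14 were in cluster 1. Mmp12 was present in 15 cells, 10 of them low-coding libraries, and Mmp2, Mmp19, Timp1 and Ctsk in none. Among lipid genes, Lpl was present in 27 cells, with a higher median in the 10 libraries (111 FPKM) than in the 21 (4.73 FPKM). Apoe and the cholesterol carrier gene Npc2 were present in 20 each and the lipid droplet gene Plin2 in 16, whereas Pparg, Fabp1, Scd1 and Cidec were found in none.

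Of the 14 interferon response genes 11 and of the 17 cell cycle genes 12 were found in under 10% of the 31 cells, and 8 and 15 in under 10% of the 21. Cxcl10 was present in 14 of 31 cells, Oasl2 in 5 and Isg15 in 3, Ifit3 and Ifi44 in none, and 1 cell held at least 50% of the interferon list. Of the cell cycle genes, 5 were found in no cell (Ccna2, Cdk1, Mcm6, Rrm2 and Aurkb), and 9 in none of the 21. The nucleotide synthesis gene Tyms was present in 19 cells, at 726 to 1477 FPKM in the 10 low-coding libraries and at most 10.96 FPKM in the 21. Birc5 was present in 9 of the 10 and 2 of the 21, Mcm2 in 8 and 0, and Pcna in 0 and 9.

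Receptor genes were found unevenly as well. Of chemokine and growth factor receptors, Csf1r was found most widely, then Ccr2 (18 cells) and the interferon gamma receptor gene Ifngr1 (17, all among the 21), and Ccr7 was found in none. Tgfbr1 was present in 16 cells, of which 10 were low-coding libraries. Of scavenger and pattern receptors, the Fc receptor gene Fcgr2b was present in 27 cells, of which 10 were low-coding libraries and 17 among the 21, Tlr2 in 20 and 18 of the 21, the C-type lectin gene Clec4e in 19 and Fcgr3 in 17, and Marco, Cd163 and Cd209a in none. Tlr2 was present in 15 of 15 cells of cluster 1 and 3 of 6 of cluster 3, and Clec4e in 14 of 15 and 1 of 6.

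Pairs of genes fixed in advance were compared with the number of cells expected to hold both if they were independent. C1qa and C1qb were found together in 6 cells against 1.35 expected, and in the 21 libraries in 6 against 2. C1qa and H2-Aa were found together in 6 cells (2.71 expected), H2-Aa and Cd74 in 14 (9.94 expected) and Ccr2 and Ly6c2 in 10 (6.39 expected). In the 21 libraries these pairs stood at 6 cells against 4, 14 against 12 and 9 against 7.62. Ccr2 was found with C1qa in 4 cells (3.48 expected) and with Cx3cr1 in 6 (6.97 expected), and Ly6c2 with Nr4a1 in 6 (7.45 expected). In the 21 libraries these were 4 against 4.57, 6 against 6.86 and 6 against 6.67, so Ccr2 with C1qa stood above expectation in all 31 and below it in the 21. Siglecf with Marco, Mrc1 with Retnla, and Arg1 with Chil3 were found together in 0 of 31 cells, since Siglecf, Marco, Retnla and Arg1 were found in none.

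The gene with the highest mean was ENSMUSG00000089855, which is not in the annotation used here, followed by the actin-binding gene Tmsb4x, Malat1, Gm28437, Lyz2, the ferritin gene Fth1, Gm37376, mt-Atp6, Gm24303 and Gm23638. Median Tmsb4x was 29772 FPKM in the 21 libraries and 54.7 FPKM in the 10, whereas the nuclear noncoding RNA gene Malat1 stood at 16641 and 13618 FPKM. The most variable genes were Ccl4, H2-Aa, Cd74 and S100a6 among annotated immune and calcium-binding genes, and 6 predicted microRNA genes (Gm25535, Gm22398, Gm23638, Gm23681, Gm26269 and Gm27857) whose medians were higher in the 10. Genes typed as microRNA took 15.8 to 44.7% of summed FPKM in the 10 and 0.114 to 3.26% in the 21. FPKM is scaled to transcript length, so few reads on a short transcript give a high value, which need not mean microRNA expression.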

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

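The alternatives with 50 FPKM and with the 21 high-coding libraries were chosen after seeing the data. In every planned clustering alternative at its own chosen number of clusters, none of the other 21 shared a cluster with the 10 low-coding libraries. All 10 stayed in cluster 2, except with genes detected regressed out, where 8 did, and where at 3 clusters 5 of the 21 joined them. The border between clusters 1 and 3 moved more. The number of clusters was 6 instead of 3 with 3000 variable genes, with k-means, with genes detected regressed out and in the 21 libraries alone. Cluster 1 then held 22.6%, 25.8%, 29.03% and 23.8% of cells, against 48.4% in the reported clusters. With 2 to 6 clusters allowed, 2 were chosen, with 67.7% of cells in cluster 1 and 0% in cluster 3. In the 21 libraries split into 2, cluster 3 held 52.4% of cells. In the 21 libraries Ptprc was found in 95.2% of cells, Adgre1 in 71.4%, and H2-Aa with Cd74 in 66.7%, and 35 functional list genes instead of 12 were in at least 75% of cells, since the 10 libraries had few of them. At 5 FPKM 7 such genes remained. At 50 FPKM 5 remained, Csf1r was found in 45.2% of cells and Ly6g in 3.23%, and the median fell to 1319 genes per cell, as a higher minimum must lower all of these. The cause of the other changes was not tested. The share of cells meeting each of the 19 cell type lists stayed in its interval under the alternatives run, of which the minimum of 1000 genes removed no cell and so tests nothing. The intervals are wide, so this is a weak check. The classical monocyte share went from 38.7% to 57.1% in the 21 libraries, just inside its upper bound of 57.8%. The differences between clusters 3 and 1 in the 13 functional lists moved by less than the pooled SD over cells of both clusters with all genes, counts scaled to library totals, k-means and the 21 libraries in 2 clusters, where the immediate early and stress difference went from 31.1 to 19.5. No paired analysis was possible because there is 1 group. A transcript not found in a cell was not detectable at that cell's depth, which does not show that it was absent. Thinning moved 7 of 343 single genes out of their intervals. It only removes reads, so it cannot show what deeper libraries would hold.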

Other observations

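The tests of receptor genes, of the 21 libraries clustered alone and of B cell RNA were chosen after the results had been seen. Cd177, known from neutrophils and some monocytes and here a member of the classical monocyte list, was present in 6 of 15 cells of cluster 1. Hopx, a homeodomain gene best known from alveolar epithelium, was present in 7 of 15 and in 1 of the 6 cells of cluster 3. No cell met the neutrophil or epithelial lists. Msr1 was present in 9 of 15 cells, Thbs1 in 10 and Ptgs2 in 9, against 0, 0 and 1 of the 6 cells of cluster 3. In cluster 3, Igf1 was present in 3 of 6 cells and Timp2 in 5, against 0 and 2 of the 15.

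The first pattern is the 10 libraries with 32.8 to 61.6% of counts on protein-coding genes. Lower depth as the whole cause is argued against, since after thinning to equal depth 10 of the 10 stayed in a cluster that held 0 of the other 21. Genomic DNA or other sequence that is not cell mRNA remains a candidate explanation. The test assumed that lung macrophages make little use of olfactory and vomeronasal receptor genes, which was not tested. Of 1358 such genes, at least 5 were found in each of the 10. At most 3 were found in any of the 21, and after thinning the numbers were at least 3 against at most 2. Coding genes of any kind that were unseen in the other high-coding libraries were also more numerous in the 10 (median 394.5, against 92 in the 21). The receptor count therefore does not single out genomic DNA. The exon length test could not decide, since coding genes unseen in the other libraries were longer where found than where not found in the 10 (median ratio 1.55) and in the 21 (1.47) alike, and that comparison with the 21 was added after the ratio was seen. Some genes recurred in all 10, among them Tyms (726 to 1477 FPKM), Lpl (48.2 to 240 FPKM), Cxcr2 (12.2 to 91.6 FPKM) and Ms4a1 (3.69 to 30.9 FPKM). The receptor gene test does not address why the same genes recurred, and this was not tested. Whether these wells held damaged cells or none stays open, and no biological explanation was tested, as the labels give a single group.

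The second pattern is the split of the other 21 libraries into monocyte-like and C1q-expressing cells. Unequal depth is argued against as the whole cause, since 21 of 21 cells kept their clusters after thinning. Immediate early and stress genes stay open: 21 of 21 kept their clusters without the stress and cell cycle lists, but only 10 of the 1000 clustering genes were thereby removed, which was judged too few to test it after the result was seen, although the prediction written before would have counted against these genes. Whether the 10 other libraries helped to set the axis could not be decided. Placing all 21 in 1 cluster would keep 15, and without the 10 libraries 16 of 21 cells kept their clusters. Cells B9, C7, D6, E12 and F10 then joined the cells of cluster 3. Of them only C7 held C1qa and C1qb (1946 and 3729 FPKM), while B9, D6, E12 and F10 had 0 FPKM of C1qa. With genes detected regressed out, 10 of 21 kept their clusters at 3 clusters, and no cell of cluster 3 was among them. The split therefore depends on that setting, and no biological explanation was tested.

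The third pattern is Ighm, the constant region gene of IgM (chromosome 12, 113418558 to 113422730), which was present in 7 cells at 193 to 1045 FPKM (452 to 5018 expected counts). Of these, 5 were in cluster 3 and the other 2, C7 and D6, were the cells k-means moved there. B cell RNA stays open: of the 7 cells, 1 held any of the B cell genes Cd79a, Cd79b, Ms4a1, Ighd, Pax5 and Fcmr, namely C7 with Cd79b (97.5 FPKM) and Ms4a1 (54.6 FPKM), and the other 6 held none. This test replaced one in which 0 of the 7 held 2 or more of Cd79a, Cd79b and Igkc, since Igkc was found in none of the 31 cells and that test passed over Ms4a1 in C7. C7 also had the most genes at 1 FPKM of the 21 libraries (3523), and whether it held 2 cells was not tested. Where in the Ighm gene the reads lie was not analysed here, so a transcript of the locus other than antibody mRNA may be the source, and no biological explanation was tested.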
